A study of Mus musculus with 18 samples.

How the data were processed

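RNA of cerebral cortex, hippocampus and brainstem of male 129SV mice, either wild type or lacking Nrf2 (gene symbol Nfe2l2), was measured on 18 Agilent 1-colour mouse arrays. The arrays fell into 6 groups, 3 regions by 2 genotypes, with 3 arrays each. Per the labels, total RNA was amplified and labelled with Cy3. Per the file headers, the scanned images were quantified with Agilent Feature Extraction, and the deposited scanner outputs give an intensity for each spot after background subtraction and spatial detrending within the array. No normalization between arrays was applied in them. The deposited table of the whole series also holds intensity values, described by the authors as normalized signal. Each of its 18 columns equalled the processed intensity of 1 array to within 0.6%, without scaling between arrays. In 11 columns that array was the one named in the title, and in 7 columns it was another one. The scanner outputs were therefore used for all comparisons, and the table served only as an alternative.

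Each array held 45018 spots, of which 43379 were no controls and represented 41174 probes. Spots marked by Feature Extraction as non-uniform or as population outliers (30 to 140 per array) were left out, and the remaining spots of a probe were averaged. The processed intensity was taken as log2 and the 75th percentile of the array was subtracted. A probe was kept when it was well above background on all 3 arrays of at least 1 group, which left 30076 probes. Gene symbols were assigned by matching the identifier of the probe to a RefSeq table. In this way 26690 probes received 1 symbol, 14484 received none and 0 received several. The probe with the highest mean stood for a gene, and probes without a symbol were tested under their own identifier. This gave 22680 tested genes, 14832 with a symbol and 7848 without. The headers name the mouse genome build mm9, whereas the RefSeq table belongs to a later build, so no coordinates are given.

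On the arrays, 65.3% to 75.1% of the spots were well above background and 0 were saturated. The 75th percentile of the processed intensity lay between 636 and 1102. The median coefficient of variation between spots of the same probe was 13.2% to 16.0%, and the spike-in fits had an r2 of 0.995 to 0.998. With 3 arrays per group, the number of arrays limited the precision.

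Genes were compared with limma 3.58.1 in R 4.3.3 by a model with 1 mean per group over all 18 arrays (12 residual and 2.34 prior degrees of freedom). Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all 22680 genes, and a gene was called at an adjusted p under 0.05. The 10 comparisons were knockout against wild type in each region and averaged over the 3 regions, the differences of the knockout effect between regions, and the differences between regions in wild-type mice. Errors after ± are standard errors unless an SD is named. The p-values measure the spread between these samples. The labels give only mouse numbers and the design text speaks of independent RNAs, so it is not known how the animals or RNAs of different regions relate.

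For a gene well above background on all 3 arrays of 1 group and on 0 of the other, the fold is given as at least N-fold. For this bound, the level on each array of the lower group was set to a floor, the 95th percentile of the probes not well above background on that array, or to the measured level where that was higher. This floor was chosen after the values were seen. No fold or difference is given, for the probe and scaling used, where neither group was above background on all arrays. The same holds where the lower group was on part.

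The 33 gene lists held 730 members, of which 708 were on the array. They were NRF2 target genes, glutathione transferases, glutathione and thioredoxin antioxidant enzymes, NADPH-generating enzymes, iron and haem handling, proteasome subunits, heat shock and unfolded protein response, cholesterol synthesis, oxidative phosphorylation, monoamine synthesis, transport and receptors, glutamate and GABA signalling, immediate early genes, circadian clock, interferon response, inflammatory cytokines and acute-phase genes, chromosome 2 neighbours of Nfe2l2, and markers of neurons, astrocytes, oligodendrocytes and myelin, oligodendrocyte precursors, microglia, endothelial and mural cells, meninges and fibroblasts, choroid plexus, ependyma and cilia, erythrocytes, cerebral cortex, hippocampus, brainstem, striatum, thalamus and habenula, cerebellum, and hypothalamus and pituitary. Lists were tested with camera (limma) with a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the 33 lists within a comparison. Camera was repeated with an estimated correlation, and fry tested whether the members of a list moved 1 way on balance. For camera, fry and the splits described further on, missing values were replaced by the mean of the group. Members are also counted as adjusted over the list alone.

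Groups, comparisons, tests, lists, alternatives and the rule for the genes named in the text were fixed before the data were examined. The rule took Nfe2l2, up to 8 called genes with a symbol per direction for each comparison of the genotypes, up to 4 called members of each list or else its member with the smallest p, the 5 called genes with the smallest p for each difference between regions, and up to 4 called members of the region lists for the differences in wild-type mice. For the differences of the knockout effect, list members were named only for lists that passed. Genes named outside this rule are said to be chosen after their values were seen. Some genes that the rule selects are not reported here.

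Slide numbers were read from the file headers. The 18 arrays lay on 5 slides, and on each slide both genotypes of a region were present in equal numbers, so a slide block left the fold changes between genotypes as they were. The comparisons of the genotypes were repeated within each slide with a model that kept 6 residual degrees of freedom, all from slides with 2 arrays per genotype. For slides with 1 array per genotype of a region, only directions and list medians are given. Whether the numbers in the titles pair the samples was checked on the residuals of the group means. Within a region, the wild-type and knockout arrays of equal number correlated across genes in 9 of 9 pairs, with r between 0.24 and 0.62 and a mean of 0.39, where arrays without a relation would give about 0. The mean of -0.18 for the 18 pairs of unequal number adds nothing, since centring on the group means forces it. All 9 pairs also share a slide, and the 6 pairs of unequal number on a shared slide had a mean of 0.072, so number and slide are confounded in part. Genes are not independent replicates, so no p is given for these values. A block for the number was therefore run for every comparison.

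The alternatives were quantile normalization, normexp background correction with an offset of 50, the table of the series, no filter and a filter on all 18 arrays, the median of a gene's probes and every probe on its own, an intensity trend with robust moderation, array weights, fits on the groups compared alone, blocks for number, animal and slide, a fold change of at least 1.5, the set tests named above, lists without shared members, and fits without each array in turn. Normexp was run on the median spot and background signals, because the files hold no mean signal. Added after the data were seen were the number block with trend and robust moderation, the levels of striatal and choroid plexus markers as covariates, and the number block with an estimated correlation in camera.

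The pipeline was tested on simulated data with changes added to 200 of 22624 genes. In cortex, 66% of changes of 1 log2 unit and 90% of 2 were recovered, with 6 false calls. Hippocampus and brainstem gave 13 false calls each. In the average, 54% of changes of 0.5 and 88% of 1 were recovered, with 8 false calls. Camera called a shift of 0.25 in all members of NRF2 targets and proteasome subunits, but only 0.5 for striatum markers. Whether this holds with residuals shared by number, slide or list members was not tested. With 200 changed genes the adjusted threshold is easier to pass than with few, so the shares of genes recovered may overstate the recovery in the data. Other software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and statmod 1.5.0.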

Results

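Gene expression was measured in cerebral cortex, hippocampus and brainstem of unstressed male 129SV mice with an intact or a disrupted gene for the transcription factor Nrf2 (Nfe2l2), which activates antioxidant and detoxification genes. Between 28326 and 32582 spots per array were well above background.

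In cortex, the normalized log2 level of Nfe2l2 was 0.79, 0.84 and 1.03 in the wild-type arrays and -8.01, -8.39 and -7.36 in the knockout arrays. In hippocampus, the wild-type levels were 0.94, 1.09 and 0.85, and the knockout levels were -3.62, -5.84 and -4.47. In brainstem, the wild-type levels were 1.10, 1.29 and 1.39, and the knockout levels were -7.33, -6.49 and -4.92. Nfe2l2 was above background in 0 of 3 knockout cortices, 3 of 3 knockout hippocampi and 1 of 3 knockout brainstems. The other Nfe2l2 probe was lower in knockout arrays of all 3 regions too, by -5.16 on the log2 scale in hippocampus. With normexp, Nfe2l2 differed by -4.32, -3.89 and -4.76 in cortex, hippocampus and brainstem. Which part of the gene was removed is not given in the sources used here, and a probe outside that part would check nothing.

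**Figure D1:**
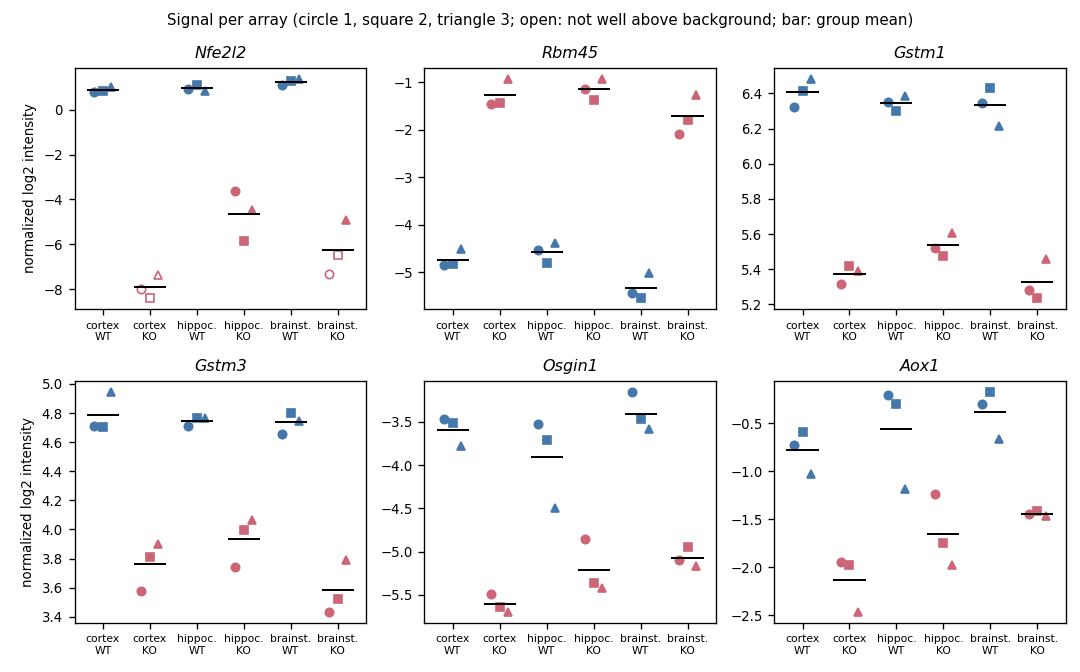
Normalized log2 intensity (vertical axis) of Nfe2l2, Rbm45, Gstm1, Gstm3, Osgin1 and Aox1 on each of the 18 arrays, by region and genotype (horizontal axis), where a symbol is 1 array, an open symbol is not well above background and a bar is the group mean. Nfe2l2 lay between 0.79 and 1.39 in wild-type arrays and between -8.39 and -3.62 in knockout arrays.

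To identify genes that depend on Nrf2 in the cortex, knockout cortex was compared with wild-type cortex (3 arrays per group). Gstm1 and Gstm3, mu-class glutathione transferases that conjugate electrophiles to glutathione, fell by 1.03 ± 0.087 and by 1.02 ± 0.12 log2 units (limma adjusted p = 6.35e-05 and 0.00245), or 2.04-fold and 2.03-fold. Osgin1, a growth inhibitor induced by oxidative stress, fell by 2.02 ± 0.22 (adjusted p = 0.00108), but by 0.72 with normexp background correction, where it was not called (adjusted p = 0.267). Rbm45, which encodes an RNA-binding protein and lies near Nfe2l2 on chromosome 2, rose by 3.46 ± 0.22 (adjusted p = 1.92e-06). Nfe2l2 was at least 150.7-fold lower as scaled here (adjusted p = 1.92e-06). Igsf1, an immunoglobulin-superfamily membrane protein, fell by 0.99 ± 0.15 (adjusted p = 0.0433). The transcript AK012417, which has no symbol and was chosen after its values were seen, was at least 2.49-fold lower (adjusted p = 0.00543). These 7 genes, 1 higher and 6 lower, were all that limma called in cortex, and 496 genes had an unadjusted p under 0.05. The groups did not overlap for any of the 7, which chance gives for 10% of genes with 3 arrays against 3.

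The second probe of Osgin1 differed by -0.61 in cortex, -0.64 in hippocampus and -0.23 in brainstem, and the second probe of Gstm1 by -1.33, -0.97 and -1.45. The other probes of Igsf1 differed by -0.59 and -0.21 in cortex. Without overlap, the 7 directions had to agree on both cortex slides. On slide 4, with 2 arrays per genotype, 7 genes were called, 5 of them among the calls above, and slide 5 holds 1 array per genotype. Igsf1 had an adjusted p of 0.0792 with the number block, of 0.0999 with the slide block, and of 0.109 to 0.334 when cortex_WT 1, 2 or 3 or cortex_KO 1 or 3 was left out. AK012417 had an adjusted p of 0.0556 without cortex_WT 2 and was not called with normexp. With the number block, Aox1, an aldehyde oxidase (-1.34 ± 0.25, adjusted p = 0.186 as fitted and 0.00572 blocked), Slc11a1, a metal transporter of phagocytes (-0.92, blocked adjusted p = 0.0346), and the integrin subunit Itga6 (-0.66 ± 0.14, 0.430 and 0.0403) were called as well.

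NRF2 target genes were lower in knockout cortex as a list, with 20 of 35 measured members negative and a median of -0.05 (camera adjusted p = 3.01e-06, adjusted p = 0.0774 with an estimated correlation). Of the 35, 3 were called over all genes and 4 adjusted over the list alone, namely Gstm1, Gstm3, Osgin1 and Aox1. Glutathione transferases had 2 of 20 members lower, over all genes and adjusted over the list alone (adjusted p = 0.00103, adjusted p = 0.276 with an estimated correlation). The list median was -0.05 and -0.15 within slides 4 and 5 for NRF2 targets and -0.08 and -0.01 for glutathione transferases. Without glutathione transferases shared by another list, the call of that list was lost.

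Striatum markers were lower in all 13 measured members in knockout cortex, with a median of -0.36 (adjusted p = 1.16e-05, adjusted p = 0.278 with an estimated correlation), and with -0.22 and -0.65 on slides 4 and 5. The dopamine receptor Drd2 (-0.72 ± 0.18), which is on the striatal and monoamine lists, passed adjusted over the list alone. Immediate early genes, which respond to neuronal activity, were lower in 17 of 21 members, with a median of -0.24 (adjusted p = 0.00277, adjusted p = 0.533 with an estimated correlation) and with -0.24 and -0.29 on the slides. Arc was at -0.70 ± 0.33. The call was lost without cortex_WT 2 (median -0.17), cortex_WT 3 (-0.21) or cortex_KO 1 (-0.16). Hypothalamus and pituitary markers were lower in 8 of 12 members (median -0.26, adjusted p = 0.00511, adjusted p = 0.276 with an estimated correlation), with Gal at -0.65 ± 0.23 and medians of -0.07 and -0.48 on the slides. This call was lost without cortex_WT 1 (median -0.18) or cortex_KO 3 (-0.075).

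Endothelial and mural cell markers were higher in 16 of 16 members (median 0.14, adjusted p = 0.00152, adjusted p = 0.278 with an estimated correlation), with Flt1 at 0.36 ± 0.17 and medians of 0.070 and 0.19 on slides 4 and 5. Microglia markers were higher in 14 of 16 members (median 0.13, adjusted p = 0.0186, adjusted p = 0.527 with an estimated correlation), with Cx3cr1 at 0.34 ± 0.18, and their median was 0.19 on slide 4 and -0.069 on slide 5. Leaving out cortex_KO 3 ended the call of both lists (medians 0.15 and 0.13), and leaving out cortex_WT 2 (median 0.064) or cortex_KO 2 (0.081) ended that of microglia. In cortex, 7 lists were called, and 13 without cortex_KO 1. Medians also moved without cortex_WT 3 for NRF2 targets (-0.10), without cortex_KO 3 for striatum (-0.23), without cortex_WT 1 for immediate early genes (-0.39) and endothelial markers (0.22), and without cortex_KO 1 (0.073) or cortex_KO 2 (0.24) for endothelial markers. With the number block, erythrocyte markers (adjusted p = 0.016) and chromosome 2 neighbours (0.0457) were called as higher in addition, but not with an estimated correlation beside the block (0.303 and 0.305).

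The remaining lists were not called in cortex. Choroid plexus markers were lower in 15 of 16 members with a median of -0.62, with 0.28 on slide 4 and -2.61 on slide 5 (adjusted p = 0.0533, Prlr -0.80 ± 0.78). Among stress and metabolic lists, the member with the smallest p was Sod3 (-0.53 ± 0.26), G6pdx (-0.19 ± 0.086), Fech (0.33 ± 0.18), Psmb7 (-0.22 ± 0.12), Atf3 (-0.66 ± 0.20), Msmo1 (0.30 ± 0.17) or Ndufa8 (0.20 ± 0.15). For signalling, clock and immune lists it was Grm3 (0.48 ± 0.21), Rorb (0.19 ± 0.14), H2-K1 (0.42 ± 0.18) or Ccl3 (1.01 ± 0.31). For cell type lists it was Eno2 (-0.19 ± 0.10), Vim (0.40 ± 0.12), Sox10 (-0.24 ± 0.15), Sox8 (-0.59 ± 0.28), Col1a1 (0.67 ± 0.31), Rsph1 (-0.35 ± 0.24) or Hba-a1 (0.44 ± 0.24). For region lists it was Foxp1 (-0.19 ± 0.13), Prox1 (-0.62 ± 0.27), Zic2 (0.25 ± 0.19), Gbx2, near background, or Hoxb6, below it in both groups. Zic2 was at -0.000679 without cortex_KO 2.

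Knockout hippocampus was likewise compared with wild-type hippocampus (3 arrays per group). Rbm45 rose by 3.43 ± 0.22 (limma adjusted p = 4.41e-06). Gstm1 fell by 0.81 ± 0.087 (adjusted p = 0.00140) and Gstm3 by 0.81 ± 0.12 (adjusted p = 0.0457), both about 1.75-fold. Nfe2l2 was 48.6-fold lower as scaled here (adjusted p = 5.10e-04). These 4 genes were the calls in hippocampus, and 301 genes had an unadjusted p under 0.05. Their groups did not overlap.

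Gstm3 in hippocampus had an adjusted p of 0.0861 to 0.2198 when any 1 of the 6 hippocampal arrays was left out, and of 0.00203 with the number block. Osgin1 was at -1.30 ± 0.22 (adjusted p = 0.114), with an adjusted p of 0.00807 with the number block, 0.0250 with the slide block, 0.0395 with quantile normalization and 0.00335 without hippocampus_WT replicate 3, against 0.0784 to 0.746 without any other hippocampal array. Aox1 was at -1.09 ± 0.25 and not called either, except with the number block, trend and robust moderation together (adjusted p = 0.0213). On slide 3, with 2 arrays per genotype, 4 genes were called, 2 of them among the 4, and slide 2 holds 1 hippocampal array per genotype.

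NRF2 target genes were lower in knockout hippocampus in 23 of 35 members (median -0.04, camera adjusted p = 6.35e-07, adjusted p = 0.0423 with an estimated correlation, and 0.0834 with the number block in addition). Of them, 2 were called over all genes and 4 adjusted over the list alone, namely Gstm1, Gstm3, Osgin1 and Aox1. The medians on slides 2 and 3 were -0.068 and -0.048. Glutathione transferases were not called (adjusted p = 0.301), with a median of 0.06 and a mean of -0.04 and with 2 of 20 lower. Erythrocyte markers were higher in 6 of 6 members (median 0.49, adjusted p = 4.13e-05, adjusted p = 0.0423 with an estimated correlation, and 0.0419 with the number block in addition), with Alas2, the erythroid enzyme of haem synthesis, at 0.53 ± 0.24 and medians of 0.477 and 0.478 on the slides.

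Choroid plexus markers were lower in 16 of 16 members in knockout hippocampus, with a median of -1.17 (adjusted p = 3.53e-06, adjusted p = 0.562 with an estimated correlation). Their mean level was 0.88, 0.38 and -3.27 in the wild-type arrays and 0.40, -3.15 and -2.60 in the knockout arrays. Enpp2 was at -0.72 ± 0.58. Beside them, oligodendrocyte and myelin markers were lower in 18 of 19 members (median -0.18, adjusted p = 3.53e-06, adjusted p = 0.481 with an estimated correlation), with Ugt8a at -0.37 ± 0.20. The calls of both lists were lost without hippocampus_WT 1 (medians -0.35 and -0.058) or hippocampus_KO 2 (-0.45 and 0.013). On slides 2 and 3 the medians were -0.50 and -1.39 for choroid plexus and -0.45 and -0.038 for myelin.

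Immediate early genes were lower in 19 of 21 members in knockout hippocampus (median -0.31, adjusted p = 9.83e-09, adjusted p = 0.215 with an estimated correlation, and 0.00661 with the number block in addition), with Ier5 at -0.24 ± 0.11 and medians of -0.33 and -0.39 on the slides. Genes of oxidative phosphorylation were higher in 38 of 40 members (median 0.10, adjusted p = 1.04e-04, adjusted p = 0.562 with an estimated correlation), with Ndufb8 at 0.15 ± 0.10 and medians of 0.044 and 0.12. This call was lost with quantile normalization and without hippocampus_KO 3 (median 0.028). Monoamine genes were lower in 27 of 34 members (median -0.12, adjusted p = 1.91e-04, adjusted p = 0.0840 with an estimated correlation), with Adra1a at -0.34 ± 0.14 and medians of -0.014 and -0.12. Without hippocampus_WT 3 (median -0.075) or hippocampus_KO 2 (-0.095) they were not called.

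Thalamus and habenula markers were lower in 10 of 14 members (median -0.13, adjusted p = 0.00367, adjusted p = 0.215 with an estimated correlation). Chrnb4, a nicotinic receptor subunit above background in only 1 of the 6 arrays, was lower adjusted over the list alone but not over all genes (adjusted p = 0.114). The medians were 0.011 and -0.20 on the slides, and the call was lost with normexp and without hippocampus_WT 2 (median -0.15) or hippocampus_KO 3 (-0.050). Hippocampus markers were lower in 12 of 16 members (median -0.12, adjusted p = 0.0302, adjusted p = 0.481 with an estimated correlation), with Prox1 at -0.42 ± 0.27 and medians of -0.23 and -0.068. This call was lost with the number block and without hippocampus_WT 1 (median -0.047), hippocampus_WT 3 (-0.15) or hippocampus_KO 2 (-0.027). In hippocampus, 9 lists were called, and 14 without hippocampus_WT 3. Without that array, the median was -0.17 for immediate early genes, 0.30 for erythrocyte and -2.55 for choroid plexus markers, while that of NRF2 targets was -0.027 without hippocampus_WT 1. Other medians that moved were those of choroid plexus without hippocampus_WT 2 (-0.63), hippocampus_KO 1 (-2.31) or hippocampus_KO 3 (-0.75), and without hippocampus_KO 3 those of myelin (-0.40) and hippocampus markers (-0.22).

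The remaining lists were not called in hippocampus. Their members with the smallest p were, among stress and metabolic lists, Slc7a11 (-0.27 ± 0.22), G6pdx (-0.074 ± 0.086), Tfrc (0.18 ± 0.10), Psma6 (0.16 ± 0.10), Atf3 (-0.41 ± 0.20) and Hmgcs1 (0.23 ± 0.13). Among signalling, clock and immune lists they were Slc1a3 (0.31 ± 0.15), Rorb (0.23 ± 0.14), Irf7 (-0.45 ± 0.20) and Ccl3 (0.72 ± 0.31). Among cell type lists they were Map2 (0.17 ± 0.10), Aldoc (0.24 ± 0.098), Lhfpl3 (0.15 ± 0.13), Tmem119 (-0.15 ± 0.11), Pdgfrb (0.20 ± 0.15), Dcn (0.58 ± 0.21) and Rarres2 (0.15 ± 0.19). Among region lists they were Rorb, Isl1 (0.58 ± 0.46), Zic2 (0.43 ± 0.19), Ghrh (0.29 ± 0.13) and, below background in both groups, Hoxd3. Without hippocampus_KO 3, Rarres2 was at -0.055 and Isl1 at -0.013.

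Knockout brainstem was likewise compared with wild-type brainstem (3 arrays per group). Rbm45 rose by 3.61 ± 0.22 (limma adjusted p = 2.15e-06). Gstm1 fell by 1.01 ± 0.087 (adjusted p = 8.80e-05), Gstm3 by 1.15 ± 0.12 (adjusted p = 7.29e-04) and Osgin1 by 1.67 ± 0.22 (adjusted p = 0.00881), but Osgin1 by 0.70 with normexp, where it was not called (adjusted p = 0.499). Nfe2l2 was lower (adjusted p = 1.10e-05), with no difference given because it was above background in only 1 knockout array. Nfe2, the erythroid relative of Nfe2l2, was at least 3.917-fold lower (adjusted p = 0.0252). Kcnv1, a modifying subunit of voltage-gated potassium channels, was called as higher (adjusted p = 0.0333), but no fold is given because it was above background in only 1 knockout array and in 0 wild-type arrays. These 7 genes, 2 higher and 5 lower, were the calls in brainstem, and 671 genes had an unadjusted p under 0.05. Their groups did not overlap, so slides 1 and 2 had to agree in direction.

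Between 4 genes (without brainstem_WT 1 or brainstem_KO 1) and 13 genes (without brainstem_KO 2) were called when 1 brainstem array was left out. Without brainstem_KO 2 Nfe2 and Kcnv1 kept their calls, whereas leaving out any other brainstem array gave adjusted p-values of 0.0515 to 0.169 for Nfe2 and of 0.0525 to 0.281 for Kcnv1. Osgin1 had an adjusted p of 0.0766, 0.0730 or 0.0674 without brainstem_WT 1, brainstem_KO 1 or brainstem_KO 3. The adjusted p of Nfe2 was 0.0619 with the number block and 0.0817 with the slide block. With normexp, Nfe2 and Kcnv1 were not called, and with quantile normalization Kcnv1 was not (adjusted p = 0.232). On slide 1, with 2 arrays per genotype, 6 genes were called, 4 of them among the 7, and slide 2 holds 1 brainstem array per genotype.

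NRF2 target genes were lower in knockout brainstem in 22 of 35 members (median -0.05, camera adjusted p = 0.00110, adjusted p = 0.395 with an estimated correlation). Of them, 3 were called over all genes and 5 adjusted over the list alone, which added Aox1 (-1.06 ± 0.25, called over all genes with the number block, trend and robust moderation together, adjusted p = 0.0244) and G6pdx (-0.34 ± 0.086), the entry enzyme of the pentose phosphate pathway. The median was -0.12 on slide 1 and 0.092 on slide 2, and the call was lost without brainstem_WT 2 (median -0.018) or brainstem_KO 2 (-0.082). Glutathione transferases had 2 of 20 members lower (adjusted p = 0.0139, adjusted p = 0.395 with an estimated correlation), with a median of -0.036 on slide 1 and 0.10 on slide 2. They were not called with the number block or without brainstem_WT 2 (median 0.089), brainstem_KO 1 (0.014) or brainstem_KO 2 (-0.083). Without members shared by another list, neither of these lists was called.

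Striatum markers were higher in 12 of 13 members in knockout brainstem, with a median of 0.44 (adjusted p = 2.18e-06, adjusted p = 0.395 with an estimated correlation). Gpr6, an orphan receptor of striatal neurons, was at 0.89 ± 0.28 and the dopamine receptor Drd1, from the monoamine list, at 1.43 ± 0.49. The mean level of the list was -1.76, -1.49 and -1.57 in the wild-type arrays and -1.12, -1.69 and -0.20 in the knockout arrays. The median was 0.19 on slide 1 and 1.15 on slide 2, and the call was lost without brainstem_KO 3 (median 0.17). Cerebellum markers were lower in 10 of 14 members (median -0.14, adjusted p = 0.0460, adjusted p = 0.395 with an estimated correlation), and Cbln3, above background in 1 knockout array, passed adjusted over the list alone. Their medians were -0.20 and 0.015 on the slides, and the call was lost with quantile normalization, with the number block and without brainstem_WT 2 (median -0.10), brainstem_WT 3 (-0.12), brainstem_KO 1 (-0.082) or brainstem_KO 2 (-0.14). In brainstem, 4 lists were called, and 1 without brainstem_WT 2 or brainstem_KO 2. The median of striatum markers was 0.74 without brainstem_KO 2 and that of cerebellum markers -0.23 without brainstem_KO 3. With the number block, interferon response was called as higher (adjusted p = 0.0377), but not with an estimated correlation beside the block (0.580).

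The remaining lists were not called in brainstem. Immediate early genes had a median of -0.02 and a mean of -0.01 while camera leaned upward (adjusted p = 0.913, Homer1 0.25 ± 0.13), and monoamine genes had a median of -0.04 and a mean of 0.03. Among stress and metabolic lists, the members with the smallest p were Gpx7 (0.25 ± 0.12), Blvra (-0.20 ± 0.076), Psmd13 (-0.24 ± 0.12), Hspb1 (-0.41 ± 0.18) and Mvd (-0.30 ± 0.12). Among signalling, clock and immune lists they were Gria1 (0.42 ± 0.15), Npas2 (0.37 ± 0.25) and C3 (-0.69 ± 0.26). Among cell type lists they were Map2 (0.24 ± 0.10), Gfap (-0.34 ± 0.16), Mal (0.35 ± 0.22), Vcan (-0.31 ± 0.14), Fcrls (0.21 ± 0.12), Pdgfrb (0.33 ± 0.15), Islr (-0.25 ± 0.14), Mlf1 (0.28 ± 0.35) and F5, which was above background in only 1 knockout array and in 0 wild-type arrays. Among region lists they were Bcl11b (0.45 ± 0.16), Mpped1 (0.23 ± 0.13), Hoxd3, above background in 2 knockout arrays, lower but higher with normexp (0.073), Tnnt1 (-0.25 ± 0.16) and Gnrh1 (0.76 ± 0.35). Mlf1 was at -0.056 without brainstem_KO 3.

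To find changes shared by the regions, the knockout effect was averaged over the 3 regions (9 arrays per genotype). Beside Rbm45 (3.50 ± 0.13, adjusted p = 1.59e-09) and Nfe2l2 (lower, adjusted p = 8.37e-09), the NRF2 target genes Gstm1 (-0.95 ± 0.050, adjusted p = 1.17e-07), Gstm3 (-0.996 ± 0.069, adjusted p = 3.72e-06), Osgin1 (-1.66 ± 0.13, adjusted p = 8.85e-06) and Aox1 (-1.16 ± 0.14, adjusted p = 0.00302) fell. Slc11a1 fell by 0.83 ± 0.093 (adjusted p = 9.48e-04) and Itga6 by 0.56 ± 0.079 (adjusted p = 0.0116). Fgfbp3, a carrier protein of fibroblast growth factors, rose by 0.45 ± 0.066 (adjusted p = 0.0176). Nfe2 was called as lower (adjusted p = 0.0263), but was above background in only 1 cortex array and 0 hippocampal arrays, and in brainstem only in wild type. The transcripts AK017540 and AK045391, chosen after their values were seen, were lower (adjusted p = 7.95e-04 and 0.0249). In all, 12 genes were called, 2 higher and 10 lower, and 1577 genes had an unadjusted p under 0.05. Gstm1, Gstm3, Nfe2l2 and Rbm45 were called in each of the 3 regions. With normexp, Rbm45 averaged 1.92. No average is given for Nfe2l2, Nfe2, AK017540 and AK045391, which were below background on part of the arrays.

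With the number block, 23 genes were called in the average, 5 higher and 18 lower, with all 12 among them. The slide block gave an adjusted p of 0.0540 for Fgfbp3, and Nfe2 was not called with it. A random block for the animal called 9 genes in the average, without Fgfbp3, Nfe2 and AK045391, and lost Igsf1 in cortex and Nfe2 in brainstem. Fgfbp3 had an adjusted p of up to 0.0609 without any 1 of cortex_WT 3, cortex_KO 3, hippocampus_WT 1, brainstem_WT 1, brainstem_WT 3 or the 3 hippocampus_KO arrays. Nfe2 kept its call only without cortex_WT 2, cortex_KO 1, hippocampus_WT 3, brainstem_WT 1 or brainstem_KO 2, and had an adjusted p of up to 0.0935 without any other array. AK045391 had an adjusted p of up to 0.0818 without any array other than cortex_WT 3, the 3 cortex_KO arrays, hippocampus_WT 3, hippocampus_KO 1 or brainstem_KO 2. Under quantile normalization and normexp, the average stayed called for Gstm1, Gstm3, Osgin1 and Aox1, while Nfe2 and AK045391 were not called with normexp.

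NRF2 target genes were lower in 24 of 35 members in the average (median -0.05, camera adjusted p = 5.12e-06, adjusted p = 0.0879 with an estimated correlation, fry adjusted p = 3.19e-04). Of them, 4 were called over all genes and 5 adjusted over the list alone, the fifth being G6pdx (-0.20 ± 0.050). The well-known targets Nqo1 (-0.13 ± 0.094), Hmox1 (-0.084 ± 0.064), Gclc (-0.068 ± 0.070), Gclm (-0.0089 ± 0.085), Srxn1 (-0.051 ± 0.053) and Txnrd1 (0.040 ± 0.085), chosen after their values were seen, did not pass in the average. Among glutathione transferases, 2 of 20 were called over all genes, and 5 passed adjusted over the list alone, with Gstm2 (-0.37 ± 0.098) and Gstm6 (-0.21 ± 0.068) lower and Gstt1 (0.22 ± 0.077) higher, in the same directions under quantile normalization and normexp. Their list was called as lower (adjusted p = 0.0289, adjusted p = 0.467 with an estimated correlation) with a mean of -0.11, although its median was 0.02 and 10 members lay on each side of 0. That call was lost with the number block, without members shared by another list and without cortex_WT 2 (median 0.025), cortex_KO 3 (0.028), hippocampus_KO 2 (-0.0070), brainstem_WT 2 (0.035) or brainstem_KO 1 (0.0034). In the average 5 lists were called, against 8 without cortex_KO 2, hippocampus_KO 1 or hippocampus_KO 3 and 3 without cortex_KO 3.

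**Figure D2:**
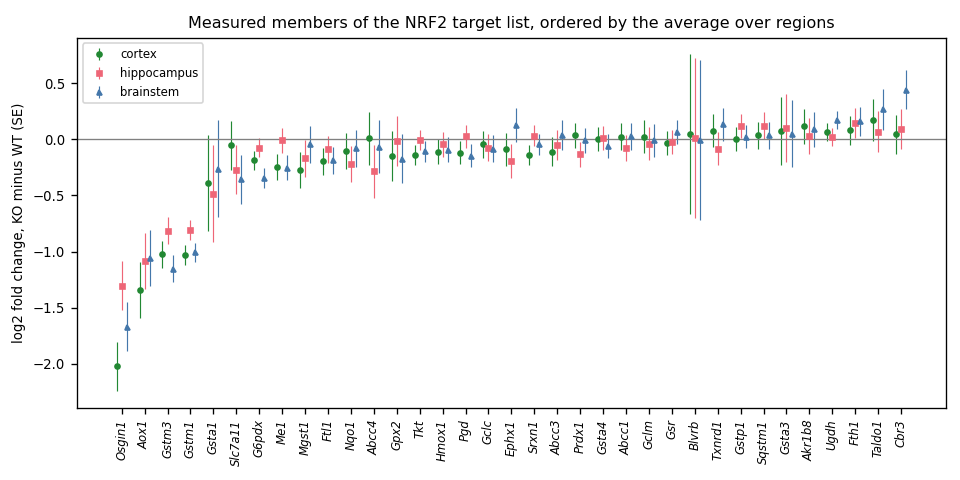
Log2 fold change, knockout minus wild type, with its standard error (vertical axis) for the 35 measured NRF2 target genes (horizontal axis, ordered by the average), with 1 symbol per region. Gstm1, Gstm3, Osgin1 and Aox1 averaged -0.95, -0.996, -1.66 and -1.16 under the scaling used and stayed lower under quantile normalization and normexp, while Nqo1 averaged -0.13.

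Chromosome 2 neighbours of Nfe2l2 were not called by camera as a list in cortex, hippocampus, brainstem or the average (adjusted p = 0.0537, 0.283, 0.386 and 0.103), and members changed in both directions. They were called as higher in cortex with the number block (adjusted p = 0.0457, but 0.305 with an estimated correlation in addition) and with normexp (0.02035), and by fry in the average (adjusted p = 0.00574). Over all genes, Rbm45 rose and Itga6 fell in the average. Adjusted over the list alone, 5 of 44 rose and 3 fell, with Agps (0.24 ± 0.056), Lnpk (0.33 ± 0.086), Slc25a12 (0.17 ± 0.052) and Itga4 (0.36 ± 0.12) higher and Hoxd1 and Ttn, below background on part of the arrays, lower. Hoxd1 had an adjusted p over all genes of 0.0813, of 0.0486 with the number block and of 0.0104 without brainstem_KO 3, but was at -0.031 with normexp. In single regions, Itga6 (cortex -0.66, hippocampus -0.48, brainstem -0.54), Ttn (lower in hippocampus) and Hoxd1 (lower in brainstem) passed adjusted over the list alone. The list median was 0.038 to 0.099 within the slides.

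Immediate early genes were lower in 16 of 21 members in the average (median -0.20, adjusted p = 0.00174, adjusted p = 0.706 with an estimated correlation), with Ier2 at -0.44 ± 0.17. Erythrocyte markers were higher in 5 of 6 members (median 0.33, adjusted p = 0.00990, adjusted p = 0.271 with an estimated correlation), and the haemoglobin genes Hbb-bt (0.38 ± 0.14) and Hba-a1 (0.36 ± 0.14) and Alas2 (0.39 ± 0.14) passed adjusted over the list alone. On single slides the erythrocyte median lay between -0.070 and 0.48, and without brainstem_WT 1 it was 0.22. Thalamus and habenula markers were lower in 12 of 14 members (median -0.080, adjusted p = 0.0203, adjusted p = 0.374 with an estimated correlation). They were not called without cortex_KO 3 (median -0.089), and the median was -0.051 without brainstem_KO 3.

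The other lists were not called in the average. Adjusted over the list alone, the chemokines Ccl3 (above background on 17 arrays) and Ccl4 (0.67 ± 0.18) rose and the stress-response factor Atf3 (-0.43 ± 0.11) fell. The adjusted p of camera lay between 0.271 and 0.897 over the 4 comparisons for glutathione and thioredoxin antioxidant enzymes, and between 0.0649 and 0.530 for NADPH-generating enzymes. It lay between 0.481 and 0.778 for iron and haem handling, 0.200 and 0.984 for proteasome subunits, 0.537 and 0.976 for heat shock and unfolded protein response, and 0.283 and 0.781 for cholesterol synthesis. The range was 0.398 to 0.897 for glutamate and GABA signalling, 0.394 to 0.984 for the circadian clock, 0.0523 to 0.495 for interferon response and 0.0649 to 0.794 for inflammatory cytokines. For cell types it was 0.0865 to 0.568 for neurons, 0.0778 to 0.651 for astrocytes, 0.631 to 0.963 for oligodendrocyte precursors, 0.0649 to 0.984 for meninges and 0.0868 to 0.897 for ependyma. For cerebral cortex and brainstem markers it was 0.0778 to 0.859 and 0.398 to 0.631.

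Members with the smallest p in the average were, among stress and metabolic lists, Gpx7 (0.17 ± 0.068), Tfrc (0.16 ± 0.060), Psmd1 (-0.11 ± 0.051), Sc5d (0.14 ± 0.061) and Ndufa8 (0.16 ± 0.086). Among signalling, clock and immune lists they were Ddc (-0.29 ± 0.098), the glutamate transporter Slc1a3 (0.30 ± 0.089) and Rorb (0.18 ± 0.082). Among cell type lists they were Map2 (0.14 ± 0.060), Aspa (-0.20 ± 0.11), Neu4 (-0.17 ± 0.098), Fcrls (0.16 ± 0.071), Pdgfrb (0.28 ± 0.084), Col1a1 (0.39 ± 0.18), Otx2 and Rsph1 (-0.14 ± 0.14). Among region lists they were Prox1 (-0.40 ± 0.16), Slc17a6 (-0.19 ± 0.14), Drd2 (-0.30 ± 0.10), Zic2 (0.32 ± 0.11) and Gal (-0.21 ± 0.13).

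To test whether the knockout effect differed between regions, it was compared in pairs of regions. Gstm1, Gstm3, Osgin1, Rbm45 and Nfe2l2, called in 1 or more regions, were not called as different between regions. In limma, 0 genes differed between hippocampus and cortex, 0 between brainstem and cortex and 0 between brainstem and hippocampus, with 189, 200 and 222 genes at an unadjusted p under 0.05. In simulated data, 0% of differences of 0.5 log2 units, 38% of those of 1 and 84% of those of 2 were recovered between brainstem and cortex. Quantile normalization gave 1, 1 and 0 genes, and the number block with trend and robust moderation 1, 0 and 0. Leaving out cortex_KO 2, hippocampus_WT 1, hippocampus_WT 2 or hippocampus_KO 1 gave 1 gene for hippocampus against cortex, leaving out brainstem_KO 2 gave 1 for brainstem against cortex, and leaving out hippocampus_WT 2 or brainstem_KO 2 gave 1 for brainstem against hippocampus. Of the lists, striatum markers had the smallest p between brainstem and cortex, with a median of 0.85 in favour of brainstem and 13 of 13 members positive (camera adjusted p = 1.10e-23, adjusted p = 0.0304 with an estimated correlation, and 0.0686 with the number block in addition), and Gpr6 (1.47 ± 0.40) passed adjusted over the list alone. Their median was 0.53 without cortex_KO 3 and 0.55 without brainstem_KO 3. Choroid plexus markers had a larger median of 1.03, but were not called without cortex_KO 3 (0.18), brainstem_WT 2 (0.90) or brainstem_KO 3 (0.40) or with an estimated correlation (adjusted p = 0.801).

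**Figure D3:**
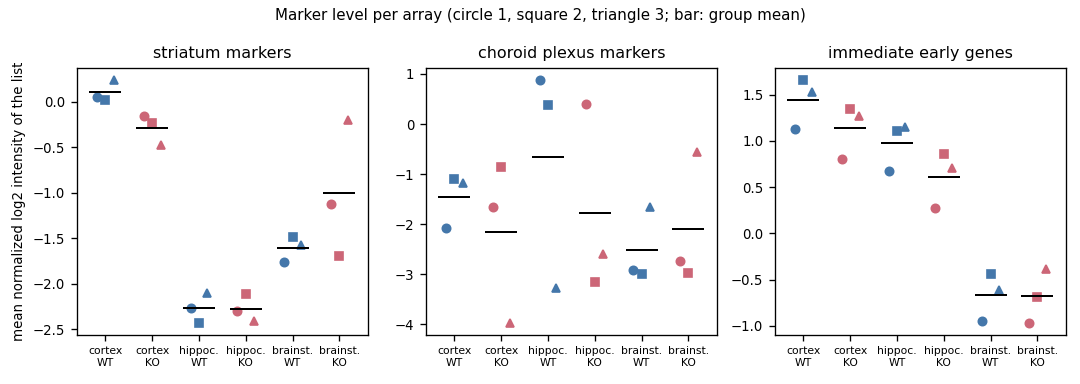
Mean normalized log2 level of striatum markers, choroid plexus markers and immediate early genes (vertical axes) on each array by region and genotype (horizontal axis), where a symbol is 1 array and a bar is the group mean. Choroid plexus markers ranged over 4.15 log2 units within the wild-type hippocampus, and striatum markers in knockout brainstem lay between -1.69 and -0.20.

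To describe the regions themselves and check the labels, wild-type hippocampus was compared with wild-type cortex (3 arrays per group). Markers of the hippocampus were higher in it for 12 of 16 members, with Dsp (5.55 ± 0.36), Lct (4.53 ± 0.24), Spink8 (4.46 ± 0.40) and the synaptic organizer C1ql2 (4.37 ± 0.32) foremost (camera adjusted p = 1.58e-13, adjusted p = 0.00690 with an estimated correlation). Cortex markers were lower for 13 of 17 members and higher for 1, with Myl4 (-3.20 ± 0.28), Lamp5 (-2.27 ± 0.17), Mef2c (-1.81 ± 0.32) and Stx1a (-1.69 ± 0.20) lower (adjusted p = 7.46e-07, adjusted p = 0.229 with an estimated correlation). Striatum markers were lower for 12 of 13 members, with Isl1 (-3.83 ± 0.46), Sh3rf2 (-3.09 ± 0.89) and Penk (-2.73 ± 0.32) (adjusted p = 5.57e-13, adjusted p = 0.129 with an estimated correlation). Of the brainstem list 4 members were higher, with Hoxb6 at least 1.52-fold, Hoxb5 at least 1.868-fold, Hoxb3, above background in 1 cortex array, and Slc6a4, above background in 2 hippocampal arrays (adjusted p = 0.0343, adjusted p = 0.670 with an estimated correlation). Among genes of lists not called were Ramp3 (-1.54 ± 0.19), Neurod1 (1.16) and the hypothalamic genes Trh (-2.76 ± 0.77), Cartpt (-2.24 ± 0.20), Pmch (1.96 ± 0.41) and Gnrh1 (-1.83 ± 0.35). In all, 3906 genes were called by limma, 1539 higher and 2367 lower, 2463 without hippocampus_WT 1, 3007 with slide as a random block and 5595 with the number block. These regions shared no slide.

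Wild-type brainstem was compared with wild-type cortex. Brainstem markers were higher for 17 of 19 members, with the hindbrain patterning genes Hoxb5 (at least 203.9-fold), Hoxb6 (at least 115.5-fold) and Hoxb2 (at least 59.9-fold) and the serotonin transporter Slc6a4 (at least 79.3-fold) foremost (adjusted p = 4.24e-13, adjusted p = 0.0254 with an estimated correlation). Thalamus markers were higher for 14 of 14 members, such as Gbx2 (4.13), Slitrk6 (3.75), Prkcd (3.65) and Tcf7l2 (3.39), and hypothalamus markers for 9 of 12, such as the neuropeptides Pmch (7.53), Hcrt (7.27), Oxt (5.31) and Avp (4.55). Their adjusted p was 4.24e-13 and 3.12e-07, and 0.00554 and 0.0254 with an estimated correlation. Brainstem samples may thus hold both tissues, which was not tested. Cortex markers were lower for 16 of 17 members, such as Myl4 (-3.94) (adjusted p = 7.48e-13, and 0.0254 with an estimated correlation). Cerebellum markers were higher for 11 of 14 members and lower for 3, with Gabra6 at least 12.65-fold, Crtam by 3.49, En2 by 3.45 ± 0.17 and Cbln1 by 2.69 (adjusted p = 6.01e-04, adjusted p = 0.0800 with an estimated correlation). Striatum markers were lower for 10 of 13 members, with Sh3rf2 at least 11.64-fold, Drd1 (-3.51) and Ppp1r1b (-2.60). Of the hippocampus list 2 members were higher and 9 lower, with Mpped1 (-2.64), Trpc6 (-2.22), Spink8 (-2.16) and C1ql2 (1.91) (adjusted p = 0.00472, adjusted p = 0.144 with an estimated correlation). Myelin markers were higher for 18 of 19 members (adjusted p = 9.32e-10, and 0.141 with an estimated correlation). Immediate early genes were lower for 17 of 21 (median -2.20, adjusted p = 5.51e-11, and 0.0998 with an estimated correlation). In all, 8108 genes were called, 4336 higher and 3772 lower, and 6975 with slide as a random block.

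Wild-type brainstem was also compared with wild-type hippocampus. Hippocampus markers were lower for 16 of 16 members, with Spink8 (-6.62 ± 0.40), Dsp (-5.70 ± 0.36) and Lct (-5.62 ± 0.24) foremost (adjusted p = 8.46e-13, adjusted p = 0.00561 with an estimated correlation). Brainstem markers were higher for 17 of 19, with Hoxb5 (6.77 ± 0.49), Hoxb6 (6.24) and the noradrenaline transporter Slc6a2 (at least 38.58-fold) (adjusted p = 4.33e-10, adjusted p = 0.0355 with an estimated correlation). Thalamus markers were higher for 13 of 14, with Tnnt1 (4.22), Synpo2 (3.46) and Slitrk6 (3.36), and hypothalamus markers for 11 of 12, with Hcrt (6.07), Pmch (5.57), Oxt (5.35) and Avp (5.06). Their adjusted p was 2.13e-11 and 2.51e-08, and 0.00561 and 0.0168 with an estimated correlation. Cortex markers were higher for 3 and lower for 11 members (adjusted p = 3.12e-04, and 0.177 with an estimated correlation). Cerebellum markers were higher for 11 and lower for 2, with Cbln1 (3.03), En2 (2.98) and Zic1 (2.98) higher (adjusted p = 6.03e-04, adjusted p = 0.0602 with an estimated correlation). The striatal genes Isl1 (4.13), Drd2 (2.68), Tac1 (1.99) and Penk (1.72) were higher. NRF2 target genes were higher for 14 of 35 members and lower for 1 (adjusted p = 0.0253, adjusted p = 0.208 with an estimated correlation). In all, 9416 genes were called, 5217 higher and 4199 lower, and 7899 with slide as a fixed block, 6450 of them shared.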

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

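The tests of the splits were planned, whereas the 9 tests of explanations for chromosome 2, the tissue markers and the table of the series and the splits drawn to part every pair were chosen after the result was seen. For 28 pairs of a gene list and a pair of regions, camera called a difference between the knockout effects in the regions, although no single gene was called as different. With an estimated correlation only striatum markers in brainstem against cortex passed (adjusted p = 0.0304), and with the number block in addition they did not (0.0686).

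Between hippocampus and cortex, the knockout effect (hippocampus minus cortex) differed for 9 lists. Striatum markers differed by a median of 0.39 (adjusted p = 1.33e-04, adjusted p = 0.624 with an estimated correlation, 12 of 13 positive, Drd2 0.64 ± 0.25) and were called without any 1 of the arrays, with 0.25 without hippocampus_KO 2. Hypothalamus and pituitary markers differed by 0.44 (adjusted p = 8.93e-04, adjusted p = 0.517 with an estimated correlation, 9 of 12 positive, Ghrh 0.58 ± 0.18), and were not called without hippocampus_KO 1 (0.42), while the median was 0.28 without cortex_WT 1 and 0.20 without cortex_KO 3. Myelin markers differed by -0.18 (adjusted p = 8.93e-04, adjusted p = 0.624 with an estimated correlation, 18 of 19 negative, Ugt8a -0.35 ± 0.28), with the call lost without cortex_KO 2 (-0.15), hippocampus_WT 1 (-0.047) or hippocampus_KO 2 (0.014) and a median of -0.40 without hippocampus_KO 3. Hippocampus markers differed by -0.11 (adjusted p = 0.00219, adjusted p = 0.517 with an estimated correlation, 14 of 16 negative, Lct -0.83 ± 0.34), but not without cortex_KO 3 (-0.10) or hippocampus_KO 2 (-0.031), and by up to -0.25 without hippocampus_KO 3. Glutathione transferases differed by 0.11 (adjusted p = 0.00880, adjusted p = 0.617 with an estimated correlation, 17 of 20 positive, Gstm6 0.40 ± 0.17), but not without cortex_KO 1 (0.11), hippocampus_WT 3 (0.058) or hippocampus_KO 3 (0.14), and by 0.17 without hippocampus_WT 2.

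The same comparison gave 4 weaker differences. Endothelial and mural cell markers differed by -0.13 (adjusted p = 0.0153, 12 of 16 negative, Pecam1 -0.31 ± 0.21), neuron markers by 0.15 (adjusted p = 0.0331, 12 of 15 positive, Stmn2 0.19 ± 0.16), meningeal markers by -0.26 (adjusted p = 0.0339, 10 of 14 negative, although Dcn was at 0.55 ± 0.30) and microglia markers by -0.076 (adjusted p = 0.0370, 13 of 16 negative, Cx3cr1 -0.44 ± 0.25). With an estimated correlation, their adjusted p was 0.624. The endothelial call was lost without cortex_WT 2, cortex_WT 3, cortex_KO 1 (-0.016), cortex_KO 3, hippocampus_WT 2 or hippocampus_KO 3. The neuronal call was lost without cortex_WT 3, cortex_KO 1 (0.049), cortex_KO 2, hippocampus_WT 1, hippocampus_WT 2 or hippocampus_KO 3. The meningeal call was lost without cortex_WT 1, cortex_WT 3, cortex_KO 1, cortex_KO 3, hippocampus_WT 2 or hippocampus_KO 3 (0.035). The microglial call stayed only without cortex_WT 1, cortex_WT 3, hippocampus_WT 2 or hippocampus_KO 2, and without cortex_WT 2 the median was 0.012. The medians reached -0.24 (endothelial) and -0.45 (meningeal) without hippocampus_KO 2 and -0.13 (microglia) without hippocampus_WT 2. With quantile normalization, the neuronal, meningeal and microglial calls were lost. Between 4 lists (without hippocampus_KO 3) and 14 (without hippocampus_KO 2) were called.

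Between brainstem and cortex, the knockout effect (brainstem minus cortex) differed for 8 lists. Striatum markers differed by 0.85 (adjusted p = 1.10e-23, 13 of 13 positive, Gpr6 1.47 ± 0.40), and hypothalamus and pituitary markers by 0.24 (adjusted p = 1.35e-04, adjusted p = 0.161 with an estimated correlation, 10 of 12 positive, Gnrh1 1.03 ± 0.50), both called without any 1 of the arrays. Their median was 0.53 without cortex_KO 3 and 0.55 without brainstem_KO 3 for striatum and 0.48 without brainstem_KO 3 for hypothalamus. Choroid plexus markers differed by 1.03 (adjusted p = 0.00126, adjusted p = 0.801 with an estimated correlation, 15 of 16 positive), but not without cortex_KO 3 (0.18), brainstem_WT 2 (0.90) or brainstem_KO 3 (0.40). Meningeal markers differed by -0.22 (adjusted p = 0.00126, adjusted p = 0.641 with an estimated correlation, 14 of 14 negative, Aldh1a2 -0.47 ± 0.36), with the call lost without cortex_KO 3 (-0.20) or brainstem_WT 3 (-0.13). Immediate early genes differed by 0.26 (adjusted p = 0.00126, adjusted p = 0.641 with an estimated correlation, 19 of 21 positive, Arc 0.73 ± 0.46), but not without cortex_WT 2 (0.15), cortex_WT 3 (0.22), cortex_KO 1 (0.074), brainstem_WT 1 (0.10) or brainstem_KO 3 (0.13), and by 0.41 without cortex_WT 1 and 0.42 without brainstem_KO 1. Cerebellum markers differed by -0.15 (adjusted p = 0.00364, adjusted p = 0.278 with an estimated correlation, 10 of 14 negative), but not without cortex_WT 2 (-0.13), brainstem_WT 3 (-0.17) or brainstem_KO 2 (-0.14), and by -0.26 without cortex_WT 3 and -0.24 without cortex_KO 3.

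Ependymal markers differed by 0.24 between brainstem and cortex (adjusted p = 0.0229, adjusted p = 0.801 with an estimated correlation, 12 of 12 positive, Rsph1 0.30 ± 0.34), but not without cortex_WT 2, cortex_WT 3, cortex_KO 3 (0.026), brainstem_WT 3, brainstem_KO 2 or brainstem_KO 3, nor with the number block or normexp. Endothelial and mural cell markers differed by -0.13 (adjusted p = 0.0229, adjusted p = 0.641 with an estimated correlation, 14 of 16 negative, Cldn5 -0.41 ± 0.30), and only without cortex_WT 1, cortex_KO 2, brainstem_WT 1, brainstem_WT 2 or brainstem_KO 3 did the call stay, with a median of -0.022 without cortex_KO 1. Without cortex_KO 2, the medians were 1.60 for choroid plexus, -0.35 for meningeal, 0.39 for ependymal and -0.23 for endothelial markers. Without cortex_WT 2, cortex_KO 3 or brainstem_WT 3, 4 lists were called.

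Between brainstem and hippocampus, the knockout effect (brainstem minus hippocampus) differed for 11 lists. Striatum markers differed by 0.31 (adjusted p = 8.30e-06, adjusted p = 0.421 with an estimated correlation, 11 of 13 positive), choroid plexus markers by 1.63 (adjusted p = 1.07e-05, adjusted p = 0.490 with an estimated correlation, 16 of 16 positive) and immediate early genes by 0.28 (adjusted p = 1.26e-05, adjusted p = 0.432 with an estimated correlation, 19 of 21 positive, Ier5 0.41 ± 0.15). These calls were lost without brainstem_KO 3, where the medians were -0.0058, 0.68 and 0.17. Otherwise, they reached 0.48 (striatum) without brainstem_KO 2, 3.02 (choroid plexus) without hippocampus_WT 3, and 0.12 and 0.48 (immediate early genes) without hippocampus_KO 1 and hippocampus_WT 1. Myelin markers differed by 0.26 (adjusted p = 3.73e-05, adjusted p = 0.453 with an estimated correlation, 18 of 19 positive, Mobp 0.42 ± 0.30), but not without hippocampus_KO 2 (0.027), and by 0.13 without hippocampus_WT 1 and 0.49 without hippocampus_KO 3. Monoamine genes differed by 0.078 (adjusted p = 0.00224, adjusted p = 0.376 with an estimated correlation, 25 of 34 positive, Drd1 1.56 ± 0.70), but not without hippocampus_WT 3 (0.025), and by up to 0.14 without brainstem_WT 2. Interferon response differed by 0.14 (adjusted p = 0.00224, adjusted p = 0.453 with an estimated correlation, 21 of 24 positive, Irf7 0.40 ± 0.28), but not without hippocampus_WT 1 (0.086), hippocampus_KO 3 (0.099) or brainstem_KO 2 (0.082), and by 0.26 without hippocampus_WT 3 and 0.22 without hippocampus_KO 1.

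Cerebellum markers differed by -0.31 between brainstem and hippocampus (adjusted p = 0.00681, adjusted p = 0.376 with an estimated correlation, 11 of 14 negative), but not without hippocampus_KO 3 (-0.11), brainstem_WT 3 (-0.25) or brainstem_KO 2 (-0.28), and by -0.185 without brainstem_KO 1. Oxidative phosphorylation differed by -0.050 (adjusted p = 0.0269, adjusted p = 0.646 with an estimated correlation, 33 of 40 negative, Cyc1 -0.21 ± 0.11), but not without hippocampus_WT 2, hippocampus_KO 3 (0.0031), brainstem_WT 2, brainstem_WT 3, brainstem_KO 1 (0.020) or brainstem_KO 2, and by up to -0.16 without brainstem_KO 3. Glutathione transferases differed by -0.080 (adjusted p = 0.0280, 18 of 20 negative, Gstm3 -0.34 ± 0.17) and hippocampus markers by 0.14 (adjusted p = 0.0280, 13 of 16 positive), with an adjusted p of 0.432 with an estimated correlation. The former kept its call only without hippocampus_WT 1, hippocampus_WT 2, hippocampus_KO 2, brainstem_WT 1 or brainstem_WT 3, with a median of -0.036 without brainstem_WT 2, and the latter only without hippocampus_WT 2, hippocampus_KO 1, hippocampus_KO 3, brainstem_WT 1 or brainstem_WT 3, with 0.092 without hippocampus_KO 2. Cerebral cortex markers differed by 0.071 (adjusted p = 0.0461, adjusted p = 0.562 with an estimated correlation, 13 of 17 positive, Bcl11b 0.68 ± 0.23), and only without hippocampus_WT 1, hippocampus_WT 2, hippocampus_KO 2 or brainstem_WT 2 did the call stay, with -0.059 without hippocampus_WT 3 and 0.30 without hippocampus_KO 2. It was lost with the number block, and that of glutathione transferases without members shared by another list. Without brainstem_KO 1, 7 lists were called, and without brainstem_KO 2 or brainstem_KO 3, 5.

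Rbm45 rose in every region beside smaller changes of other chromosome 2 neighbours of Nfe2l2. Array scaling or background correction is argued against, because Rbm45 stayed higher by 1.92 in the average under normexp. Unadjusted p-values under 0.05 in the average were more frequent among the other 43 neighbours (18.6%) than among all other genes (6.92%, Fisher's exact p = 0.00868). This counts neighbours that belong to the pattern and takes genes as independent, so it decides nothing. A changed sequence or regulation of the targeted chromosome segment and loss of the NRF2 protein acting on Rbm45 from a distance cannot be told apart, because 0 knockout arrays have an intact locus.

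Choroid plexus markers were lower in knockout hippocampus, and striatal markers were lower in knockout cortex and higher in knockout brainstem, but these 3 calls of camera were lost with an estimated correlation (adjusted p = 0.562, 0.278 and 0.395). Array scaling or background correction is argued against, because the difference of striatal markers between brainstem and cortex was 0.70 or more under quantile normalization and normexp. Choroid plexus markers ranged over 4.15 log2 units within wild-type hippocampus, more than the genotypes differed, so unequal amounts of choroid plexus in the dissected hippocampus may explain them. Striatal markers moved in opposite directions in cortex and brainstem for 12 of 13 members, and unequal amounts of striatal tissue in the dissections cannot be told apart from a region-dependent effect of the knockout on striatal genes (adjusted p = 0.0304, and 0.0686 with the number block in addition), because no array measured the tissue share independently.

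In the table of the series, 7 columns held the values of another array than their title names. That the scanner outputs carry wrong sample labels is argued against by Nfe2l2, which went against the genotype label in 0 of 18 outputs. In the table, Nfe2l2 went against the genotype in the title in 2 columns, consistent with the column titles of the series table being out of order.

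Splits of the same arrays into other groups were fitted in the same way. For genes in cortex, hippocampus and brainstem, the 10 splits are too few for a share under 0.05, with 7, 4 and 7 calls for the genotypes and at most 1, 87 and 2 for another split, and 1, 3 and 1 splits gave as many as the real one. The 87 came from hippocampus_WT 1, hippocampus_WT 2 and hippocampus_KO 1 against the others, the arrays with the higher choroid plexus markers, which points to a structure of the samples, and 4 genes were called for the genotypes within slide 3, which holds 2 hippocampal arrays per genotype. Among the 4 splits that part every pair of equal number, the highest other had 1, 0 and 1 calls. In the average, 2 of 100 splits gave as many as the 12 calls, the real split included (highest other 12). Among 100 of the 256 splits that part every pair of equal number, only the real one did (highest other 2). The 12 include Nfe2l2 and Rbm45, so chance stays open for weaker calls. For the differences between regions, 0 genes were called, so each of the 100 splits gave as many by construction and nothing follows about chance. Other splits gave up to 48, 520 and 27 genes, which points to a structure of the samples too. For the regions in wild-type mice, 10 splits are too few for a share under 0.05, with 3906, 8108 and 9416 genes and 0 for any other split.

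For the lists, 10 splits are again too few in single regions, where 7, 9 and 4 lists were called and at most 9, 13 and 4 in another split, and 3, 9 and 3 splits gave as many. In the average, 72 of 100 splits gave 5 lists or more (highest other 11). For the differences between regions, 39, 9 and 7 of 100 splits gave as many lists as the 9, 8 and 11 reported (highest other 15, 14 and 16). Chance can therefore not be excluded for the number of lists called in these.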

How the results depend on the processing

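The tests with the number block combined with trend and robust moderation or with an estimated correlation were chosen after the data were seen. Where no reason is given, the cause was not tested.

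With the table of the series, whose columns were partly out of order, 0 genes were called by limma in cortex, hippocampus, brainstem and the average and 4 for wild-type hippocampus against cortex. Its Nfe2l2 values were -6.04, -5.33, -7.51 and -6.29 for the probe used and -5.27, -4.73, -7.15 and -5.71 for the other, and neither was called. With it, Rorb (-0.12), Prlr (0.64), Rsph1 (0.043) and Prox1 (0.23) in cortex and Slc7a11 (0.069), G6pdx (0.058), Atf3 (0.021), Adra1a (0.046), Ier5 (0.19) and Dcn (-0.15) in hippocampus reversed.

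Normexp gave 4 genes in brainstem and 14, 8 and 10 lists in cortex, brainstem and the average, and reversed Hoxd3 in brainstem (0.073) and Chrnb4 in the average (0.024). Of 30 calls of named genes, 7 were lost with normexp, 1 with quantile normalization and 2 with the number block. Normexp shrinks low signals, and the lost genes included Osgin1 in cortex (adjusted p = 0.267) and brainstem (0.499). Quantile normalization gave 1 gene for hippocampus against cortex, 1 for brainstem against cortex, and 12 and 10 lists in cortex and the average. Fits on the arrays of the 2 groups alone, with fewer residual degrees of freedom, gave 1 gene in hippocampus and 0 in brainstem. Array weights gave 7 genes in hippocampus and 8865 for wild-type hippocampus against cortex, where a fold change of at least 1.5 left 2514. A filter on all 18 arrays left 4 genes in brainstem, since genes with lower signal were not tested.

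The replicate block on the number gave 23 genes in the average. It gained Aox1 (0.00572), Slc11a1 (0.0346) and Itga6 (0.0403) in cortex, Osgin1 in hippocampus (0.00807) and Hoxd1 (0.0486) and Kcnv1 (0.0280) in the average. It lost Igsf1 in cortex and Nfe2 in brainstem and changed no other call of a gene named in the report. With trend and robust moderation in addition, 11 genes were called in cortex, 7 in hippocampus and 1 for hippocampus against cortex.

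Camera with an estimated correlation called 0, 2, 0 and 0 lists in cortex, hippocampus, brainstem and the average and 0, 1 and 0 for the differences between regions, and with the number block as well 0, 2, 0, 0, 0, 0 and 0. Fry called 1, 0 and 0 lists in the single regions and 0 in each difference between regions. Members of 1 list only gave 1 list in brainstem and 3 in the average.

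Leaving out 1 array gave 5 to 8 genes in cortex, 3 to 6 in hippocampus, 4 to 13 in brainstem and 9 to 13 in the average. It gave 0 to 1 for each difference between regions, and 2463 to 3484, 6596 to 7532 and 7835 to 9190 for the wild-type regions. For lists, it gave 5 to 13, 9 to 14, 1 to 6 and 3 to 8, and 4 to 14, 4 to 9 and 5 to 14 for the differences. Zic2 in cortex lay between -0.000679 and 0.43, Rarres2 in hippocampus between -0.055 and 0.36, Isl1 in hippocampus between -0.013 and 1.08 and Mlf1 in brainstem between -0.056 and 0.48. Calls of named genes were lost in 57 of 324 such fits.

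Genes near background have only a bound, as Nfe2 and AK012417, or no fold, as Kcnv1.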

Other observations

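The tests in this part were chosen after the data were seen. Genes differed between the numbers of the arrays. Numbers 1 and 2 shared a slide in cortex and brainstem and numbers 2 and 3 in hippocampus, so a model could hold both number and slide. In limma, 5175 of 22680 genes varied with the number (F-test, 8315 at an unadjusted p under 0.05), among them Gstt2, a theta-class glutathione transferase (-0.68 for number 3 against 1), the hormone-sensitive lipase Lipe (-0.49), the cytokine Flt3l (-0.70), the polarity gene Pard3b (-0.68), Ccdc141 (-0.63) and the ubiquitin ligase Ttc3 (0.56). Immediate early genes had a median of 0.38 for number 2 against 1 (camera adjusted p = 0.00447 with an estimated correlation) and of 0.27 for number 3 against 1 (0.0308). Genes of heat shock and the unfolded protein response had a median of 0.22 for number 3 against 1 (0.0273) and of 0.25 for number 3 against 2 (0.00665). With slide in the model, which left 7 residual degrees of freedom, limma called 0 genes for the number (3448 at an unadjusted p under 0.05) and 365 for the slide (2423), and the differences of number 3 against 1 for the genes named lay between -0.75 and 0.46. Only heat shock and unfolded protein response for number 3 against 2 (median 0.33, adjusted p = 0.0118) then passed with an estimated correlation, and the medians of immediate early genes were 0.53 (0.0805) and 0.44 (0.101). Across regions, the residuals of arrays of equal number correlated with a mean r of 0.25 within a genotype (-0.052 to 0.71) and 0.23 between genotypes (0.0052 to 0.64), and none of these pairs shared a slide. The highest values came from number 3 of cortex and brainstem, and for number 1 several lay near 0. What the numbers stand for is not given in the sources used here.

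Nfe2l2 signal above background was left in 3 of 3 knockout hippocampi, at 4.19%, 0.900% and 2.31% of the wild-type mean, and in 1 of 3 knockout brainstems at 1.38%, against 0 of 3 knockout cortices. Nfe2l2 was lower with normexp in all 3 regions, but with arrays below background the regions cannot be compared.

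With the levels of striatal and choroid plexus markers as covariates, 7, 4, 5 and 10 genes were called in cortex, hippocampus, brainstem and the average, with 6, 3, 5 and 10 of them among the calls without covariates. Aox1 in cortex (adjusted p = 0.0478) and Osgin1 in hippocampus (0.0442) were called with them, and Igsf1 in cortex, Gstm3 in hippocampus and Kcnv1 and Nfe2 in brainstem were not.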
